A study of Mus musculus with 41 samples.

How the data were processed

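Messenger RNA was measured in 41 kidney libraries from mice. Per the labels' protocols, RNA was extracted from a frozen section of the kidney pole with a column kit, and 3′ end libraries were made from 500 ng of RNA with the QuantSeq 3′ FWD kit. The values are whole-number counts per gene in a single deposited table of 48795 genes and 41 columns, with no normalization. Per the submitters' processing notes, the counts of the first cohort were made with Trimmomatic, STAR and HTSeq 0.6.1 on the build GRCm38 (mm10). For the second cohort the same notes name STAR 2.7.11b and GRCm39. The version of the other tools, the annotation release, the strand setting of the counting and the counting tool of the second cohort are not given in the sources used here. Both cohorts are listed over the same gene identifiers although the notes name different builds, so counts were compared only within a cohort except where a joint fit is named.

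Gene symbols were matched to the identifiers for 48349 genes, and 446 identifiers had no symbol. Positions are from the GENCODE annotation of GRCm38, the build named for the first cohort, and no positions are given for GRCm39. Columns were joined to groups through the library numbers in the labels. A single column is named as undetermined, its label gives no group, and it was left out of all comparisons. The replicate numbers in the titles did not pair samples in any comparison, since correlations of deviations from the group means between equal numbers ran from -0.424 to 0.447.

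Library blocks were inferred from the sample-sheet and library numbers in the column names, and the labels do not name batches. In the first cohort the sheet numbers 11 to 17 occur 2 times, and the set with the higher library numbers is block 2b. In the second cohort each sheet number occurs once, 1 to 10 in block 2a and 18 to 23 in block 2c, and the gap between them is filled by the numbers of block 2b, so the cohorts may share a sheet. Blocks 1a and 1b, and 2a and 2c, part where the library numbers, which rise with the sheet number, start again. The first cohort falls into blocks 1a, 1b and 2b and the second into 2a and 2c. UIRI d7 of the first cohort has no library in block 2b, and UIRI d3 of the second has none in block 2c. Comparisons were repeated with the block as a covariate and within each block where both groups had at least 2 libraries.

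Each cohort was fitted on its own, all groups together, with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. Counts were scaled by the trimmed mean of M values (TMM), genes were kept by filterByExpr with the groups, and p values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. This left 15701 genes in the first cohort and 15543 in the second. Group values are CPM on the TMM-scaled library size, as mean ± SD, and the standard error of a log2 fold change was taken as its size over the square root of F. For the column without a group, plain CPM with Wilson intervals were computed from the counts. The intervals cover counting error alone. A difference between cohorts was tested as an interaction in a joint edgeR fit of 16606 genes, which was added after the data had been seen.

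Gene lists were tested with camera from limma 3.58.1 on the same counts and design, with the preset correlation of 0.01 and adjusted over the lists. The test was repeated with a correlation estimated per list and with fry. A list is said to be called when its adjusted p with the preset correlation passed 0.05, and the result with an estimated correlation is given beside it. The 34 lists of the report were fixed beforehand from general knowledge and hold tubular injury, failed repair, cell cycle, progenitor, matrix, leukocyte, nephron segment, metabolic, stress and neighbouring tissue genes. Members are counted at the adjusted p over all genes and again adjusted over the list alone. The lists share few members, the most being 4 between tubular injury and epithelial progenitor genes. A further 5 lists were made after values had been seen and appear only in the closing section.

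Genes are named by a rule fixed beforehand. It takes, per comparison, up to 6 genes in each direction with the largest log2 fold change among genes that passed the test, reached a group mean of 5 CPM and did not overlap between groups, leaving out unnamed, immune receptor, mitochondrial, ribosomal and histone genes. It adds up to 4 members of each list with the smallest adjusted p and a set of 28 marker genes in every comparison. Genes whose symbols stand for near-identical copies cannot be told apart with certainty by 3′ reads.

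Depth was measured as the total count per library, and the number of detected genes was compared after thinning each library to 5090418 counts. Total counts, detected genes, mitochondrial share, hemoglobin share and the share of Gm42418, a gene that overlaps ribosomal RNA, were compared between groups with two-sided exact permutation tests, adjusted over 45 tests. With 6 against 6 libraries the smallest p these can give is 0.00216, and with 4 against 6 it is 0.00476. Principal components used the 2000 most variable genes as log2 CPM with a prior count of 2.

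The reversal of injury changes was described by the correlation across genes and the share of opposite signs. Because the UIRI d7 libraries enter both fold changes, the same values were computed in 10 simulated sets of unchanged groups, with the UIRI d7 libraries divided 3 and 3 in 20 ways, and with the second cohort's nephrectomy effect. Expected overlaps of call lists are those of independent lists and are given only for comparisons that share no library.

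The tests were checked on simulated counts drawn from the means and library sizes of the real libraries, with 100 genes changed 2-fold and 100 changed 4-fold. In the first cohort edgeR recovered 57 and 94 of them for UIRI d3 against Control (15485 genes tested, 9 false calls), 57 and 96 for UIRI d7 against Control (15476 genes, 8 false), and 54 and 98 for UIRI+Nx d7 against Control (15492 genes, 7 false). It recovered 50 and 92 for UIRI+Nx d7 against UIRI d7 (15466 genes, 4 false), 49 and 96 for UIRI d7 against UIRI d3 (15497 genes, 5 false), and 50 and 95 for UIRI+Nx d7 against UIRI d3 (15489 genes, 7 false). For the second cohort it recovered 68 and 95 for UIRI+Nx d7 against UIRI d7 (15244 genes, 9 false), 73 and 100 for UIRI d7 against UIRI d3 (15327 genes, 7 false), and 67 and 93 for UIRI+Nx d7 against UIRI d3 (15285 genes, 12 false). For UIRI+Nx d7 against UIRI d7 DESeq2 recovered 67 and 95 with 24 false calls in the first cohort and 77 and 97 with 27 in the second, and limma voom 50 and 91 with 3 and 67 and 95 with 14. Among simulated unchanged lists camera called 1 of 34 for UIRI d3 against Control and 0 for UIRI+Nx d7 against UIRI d7 in either cohort. Counts were drawn independently between genes, so this does not test camera under correlated genes. The changed genes were taken only above a minimum mean count, so recovery at lower counts was not measured.

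The alternatives tried were DESeq2 1.42.0, limma voom with sample quality weights, median-of-ratios and upper-quartile scaling, no filter on low counts, a filter of 1 CPM in 6 libraries (4 in the second cohort), fits of only the 2 groups compared, the replicate number as a block, the range of library numbers in the first cohort, library sizes without mitochondrial and globin genes, and each library left out in turn. Alternatives added after the data had been seen were the library block, the second cohort's nephrectomy effect in the reversal, list tests without single libraries, leaving out UIRI d3 replicate 2 with UIRI d7 replicate 4, and library sizes without Gm42418 and mitochondrial ribosomal RNA. Splits of the libraries into other groups of the same sizes were drawn 100 times per comparison, the real split included.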

Results

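RNA was sequenced from kidneys of mice after a single kidney had been injured by closing its blood supply and reopening it, called unilateral ischemia-reperfusion injury (UIRI). Per the labels the mice of the first cohort were males 8 to 10 weeks old, the left kidney was ischemic for 21 min at a core temperature of 34 °C, and on day 3 the uninjured kidney was either removed (nephrectomy, Nx) or left in place. The design in the labels describes 4 groups of 6, which are those of the first cohort, and sex, age, ischemia time, temperature and day of nephrectomy are not given for the second. The first cohort held 24 libraries in 4 groups of 6, named Control, UIRI d3 (harvested on day 3), UIRI d7 (harvested on day 7) and UIRI+Nx d7 (nephrectomy on day 3, harvested on day 7). The plan of the tests lists UIRI d7 as sham nephrectomy, so UIRI d7 and UIRI d3 may differ in that operation as well as in day. The second cohort held 16 libraries in 3 groups, UIRI d3 (n = 6), UIRI d7 (n = 6) and UIRI+Nx d7 (n = 4), without a Control group. Its titles carry WT, read here as wild type, and write IR, while its treatment tags read UIRI and UIRI+Nx; no genotype is given for the first cohort, so the use of the same group names for both is an inference. Another library carried no group in its label and enters no comparison. The libraries read the 3′ ends of messenger RNA from a section of the kidney pole, and the deposited table gives whole-number counts for 48795 genes.

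Total counts per library ran from 5090418 to 33362940. The 6 Control libraries held 12888852 to 30753380 counts, the UIRI d3 libraries 9271486 to 15611432, the UIRI d7 libraries 5090418 to 17591854 and the UIRI+Nx d7 libraries 5579718 to 19039076. In the second cohort the ranges were 12431540 to 16018040, 5387275 to 33362940 and 8593244 to 26290199. Mitochondrial transcripts took 8.32% of counts in Control (SD 1.54, n = 6), 4.22% in UIRI d3 (SD 0.772), 2.77% in UIRI d7 (SD 0.577) and 4.62% in UIRI+Nx d7 (SD 0.896). Each of the 3 injured groups had a lower mitochondrial share than Control, with p = 0.00216 in a two-sided exact permutation test for each, the smallest p that 6 against 6 libraries allow (adjusted p = 0.0194 over 45 such tests). The first principal component held 48.3% of the variance in the first cohort and separated Control from the 3 injured groups, and the second held 13.2%.

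**Figure D1:**
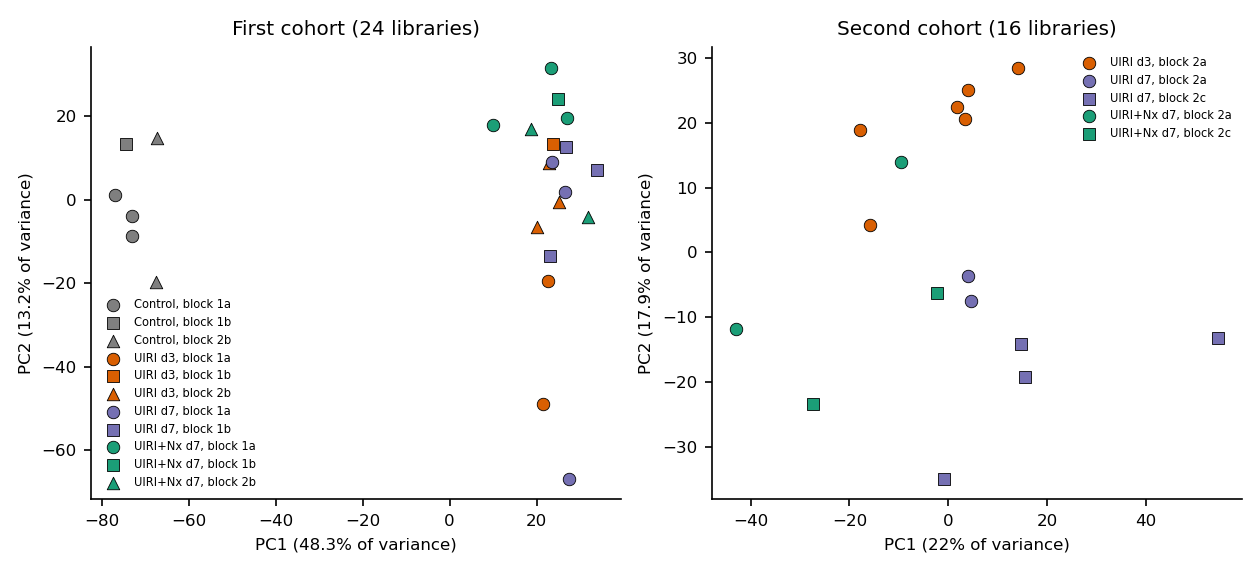
Scores of the libraries on the first and second principal component, fitted for each cohort alone, with the percent of variance on each axis, points for libraries and colours for groups. In the first cohort the Control libraries lie between -76.89 and -67.3 on the first component, while UIRI d3 replicate 2 (-48.92) and UIRI d7 replicate 4 (-66.71) stand apart on the second.

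The comparison of UIRI d3 with Control asks how ischemia had altered the kidney by the day of nephrectomy. Havcr1 (ENSMUSG00000040405, on chromosome 11 from 46735080 to 46779578 in GRCm38), which encodes the injury marker KIM-1 of the proximal tubule, rose from 4.32 ± 1.36 to 1000 ± 352 CPM (n = 6 per group, log2 fold change 7.86, SE 0.47, adjusted p = 3e-12 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Krt20, a keratin of injured tubules, rose from 0.528 ± 0.307 to 82.4 ± 22.6 CPM (log2 fold change 7.26). Cxcl2, an attractant of neutrophils, rose from 0.0486 ± 0.102 to 26.8 ± 8.42 CPM (log2 fold change 9.11). Foxm1, a driver of mitotic gene expression, rose from 2.59 ± 0.697 to 31 ± 5.6 CPM (log2 fold change 3.57, SE 0.21, edgeR adjusted p = 1.65e-12). Egf, made by the distal nephron, fell from 578 ± 165 to 23.5 ± 3.2 CPM (log2 fold change -4.62, SE 0.34, edgeR adjusted p = 6.44e-11). Slc22a7, an organic anion transporter of the proximal tubule, fell from 140 ± 45.6 to 1.02 ± 0.875 CPM (log2 fold change -7.16). The acute phase gene Saa3 rose by a log2 fold change of 9.48 (SE 1.59), but its values in UIRI d3 ran from 1.22 to 312 CPM, and replicate 3 of that group also held the highest Lcn2.

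Among injury genes, 30 of 32 measured tubular injury genes and 15 of 16 genes of failed proximal tubule repair rose, and 30 and 16 did so when adjusted over the list alone. Vcam1, an adhesion molecule found on tubule cells that do not recover, rose from 26.3 ± 7.63 to 393 ± 108 CPM (log2 fold change 3.90). The median log2 fold changes of these lists were 3.07 and 1.98. Of 15 epithelial progenitor genes 8 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.73), among them Sox9, a transcription factor of regenerating tubules, which rose from 5.61 ± 1.24 to 174 ± 76.9 CPM (log2 fold change 4.96). The progenitor gene Pax2 did not change, at 50.4 ± 33.4 against 54.8 ± 20.9 CPM (log2 fold change -0.12, SE 0.37, edgeR adjusted p = 0.838). Of 21 YAP-TEAD targets 8 rose and 1 fell (median 0.38, adjusted p = 0.119 with an estimated correlation), among them Myof, with a log2 fold change of 2.37.

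Cell cycle genes rose as groups. Of 46 DNA replication and S phase genes 43 rose and 1 fell, with a median log2 fold change of 2.09. Of 50 G2 and mitosis genes 48 rose and 1 fell, with a median of 3.63 (43 and 48 rose adjusted over each list alone). Mcm3, a part of the replication helicase, rose from 8.4 ± 1.53 to 67.7 ± 11.8 CPM (log2 fold change 3.01). Top2a, the topoisomerase of dividing cells, rose from 14.3 ± 1.72 to 233 ± 67.9 CPM (log2 fold change 4.02). Of 25 p53 targets and cell cycle inhibitors 11 rose (median 0.37), led by Cdkn1a, the inhibitor p21, which rose from 9.09 ± 1.43 to 70 ± 4.25 CPM (log2 fold change 2.94). Of 30 ribosome biogenesis and Myc genes 18 rose and 2 fell (median 0.71).

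Genes of differentiated tubule segments fell. Of the measured members, 38 of 45 proximal tubule, 28 of 32 fatty acid oxidation and 53 of 69 oxidative phosphorylation genes fell, and 40, 28 and 62 did so when adjusted over the list alone. Their median log2 fold changes were -1.52, -0.92 and -0.85. In the distal convoluted and connecting tubule list 11 of 12 genes fell (median -1.84), among them Calb1, a calcium buffer, which fell from 638 ± 134 to 35.9 ± 18.3 CPM (log2 fold change -4.15). Of the loop of Henle list 8 of 13 fell and 1 rose (median -0.80). Of the intercalated cell list 10 of 12 fell (median -1.37), among them the anion exchanger Slc4a1, with a log2 fold change of -2.89. Of 12 principal cell genes 7 fell and 1 rose (median -0.94, adjusted p = 0.111 with an estimated correlation). Of 25 cholesterol synthesis genes 11 fell and 1 rose (median -0.54, adjusted p = 0.37 with an estimated correlation), among them Cyp51, which fell from 555 ± 76.1 to 134 ± 6.58 CPM (log2 fold change -2.05).

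Matrix and fibroblast genes rose at 37 of 40 members and fell at 1 (median 1.79), with Col1a1, the main fibrillar collagen chain, rising from 63.4 ± 14.8 to 532 ± 82.6 CPM. Among leukocyte genes 28 of 35 macrophage and monocyte members rose and 1 fell (median 1.91). Of cytokine and chemokine genes 20 of 26 rose and 2 fell (median 2.03). Itgam, an integrin of myeloid cells, rose from 0.735 ± 0.432 to 15.7 ± 4.73 CPM (log2 fold change 4.38). The 9 measured neutrophil genes rose (median 5.34, adjusted p = 0.105 with an estimated correlation). Of 17 immediate early and heat shock genes 8 rose (median 0.81, adjusted p = 0.0881 with an estimated correlation).

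The remaining lists were not called in this comparison. In camera, the gene list test used here, lymphocyte and interferon genes had medians of 0.28 for T and NK cells (3 of 14 rose, camera adjusted p = 0.377), 0.16 for B and plasma cells (camera adjusted p = 0.798) and 0.31 for the interferon response (3 of 25 rose, camera adjusted p = 0.34). Metabolic and stress lists had medians of -0.08 for glycolysis (camera adjusted p = 0.407), -0.15 for NRF2 targets (4 of 20 rose and 5 fell, camera adjusted p = 0.575) and -0.47 for the circadian clock (3 of 17 rose and 7 fell, camera adjusted p = 0.057). Cell type lists had medians of -0.23 for podocytes (camera adjusted p = 0.372), -0.08 for endothelium (camera adjusted p = 0.407) and 0.31 for smooth muscle and mesangium (camera adjusted p = 0.588). Lists that mark neighbouring tissue or blood had medians of -0.93 for urothelium (camera adjusted p = 0.828), -0.15 for adipocytes (camera adjusted p = 0.8), 1.06 for adrenal cortex (3 of 9 genes measured, camera adjusted p = 0.575) and -1.37 for red blood cells (camera adjusted p = 0.554).

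In the edgeR test 5132 of 15701 genes changed, of which 2793 rose and 2339 fell, 1795 and 1161 of them by more than 2-fold. In 2844 of the changed genes every library of a group lay above every library of the other. Chance gives this for 0.216% of genes that no test has picked, so that share is no yardstick for picked genes. Of the 34 lists 21 were called by camera, 13 higher and 8 lower, and 16 of them were also called with an estimated correlation; median, mean and test differed in sign for the glycolysis and the B and plasma cell lists. Within library blocks, read from the sample-sheet numbers, 2729 genes changed in block 1a (2 against 3 libraries) and 2366 in block 2b (3 against 2 libraries).

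**Figure D2:**
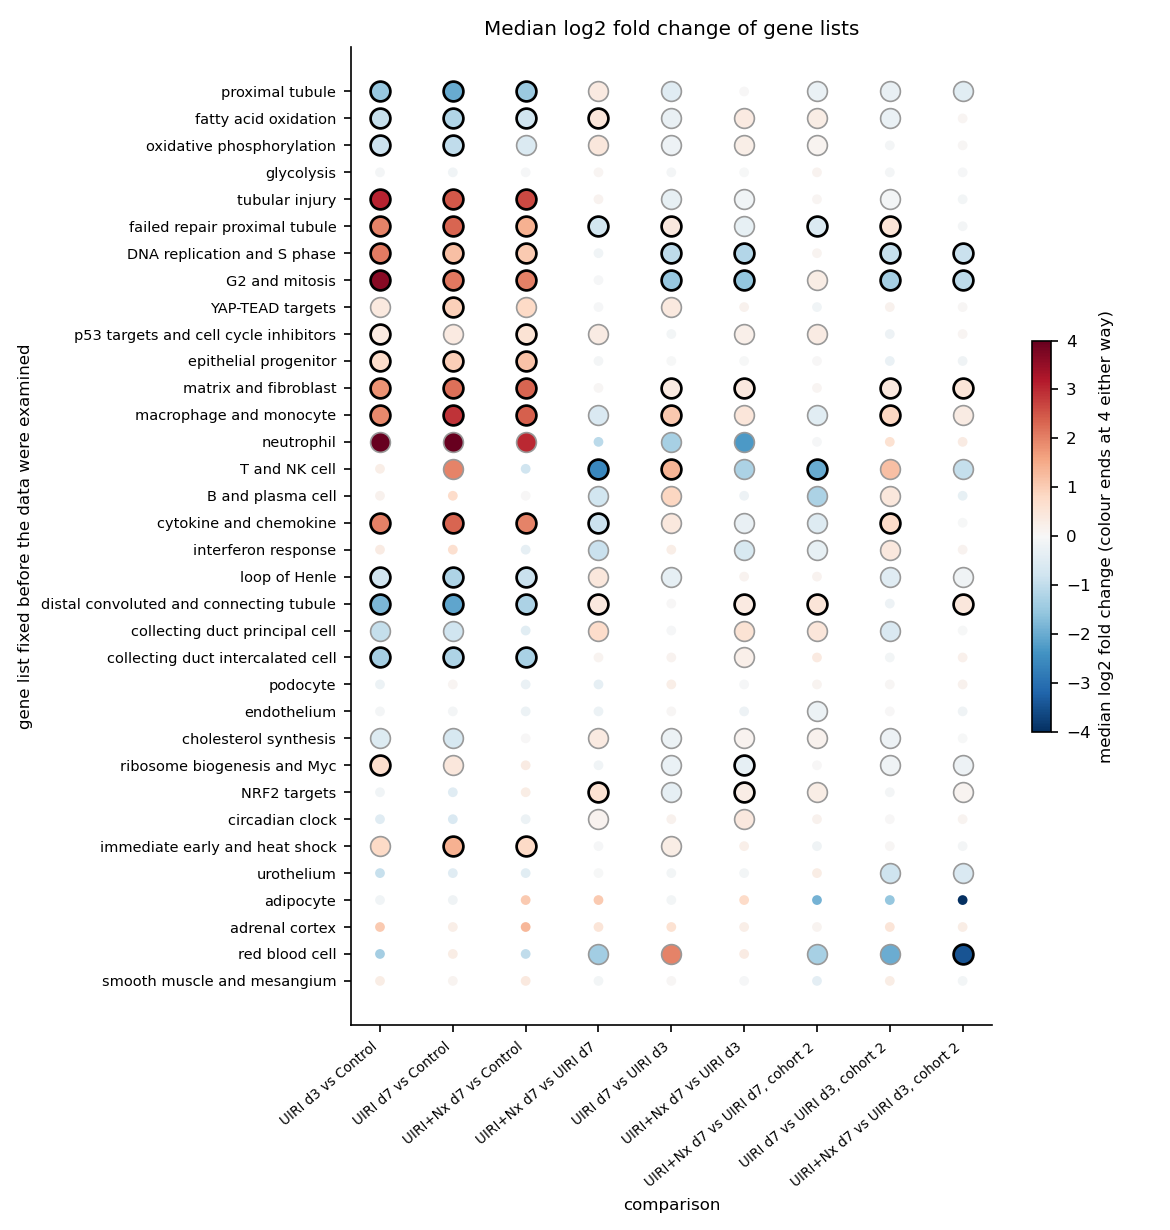
Median log2 fold change (colour) of the 34 gene lists fixed beforehand (vertical axis) in each comparison (horizontal axis). Large circles mark lists called by camera, with a black edge where the call also held with an estimated correlation and a grey edge where it did not; small dots were not called. The G2 and mitosis list goes from 3.63 in UIRI d3 against Control to -1.51 in UIRI d7 against UIRI d3.

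The comparison of UIRI d7 with Control asks which changes were present a week after ischemia with the other kidney in place. Havcr1 rose from 4.32 ± 1.36 to 677 ± 259 CPM (n = 6 and 6, log2 fold change 7.30, SE 0.46, edgeR adjusted p = 4.83e-12). Vcam1 rose from 26.3 ± 7.63 to 514 ± 140 CPM (log2 fold change 4.29, SE 0.25, edgeR adjusted p = 1.34e-12). Cd44, a hyaluronan receptor of injured epithelium, rose from 3.75 ± 1.06 to 107 ± 38.9 CPM (log2 fold change 4.85). Lyz2, the lysozyme of myeloid cells, rose from 26.8 ± 5.59 to 603 ± 188 CPM (log2 fold change 4.49). Cdkn2a, an inhibitor tied to cell senescence, rose from 0.101 ± 0.0457 to 4.06 ± 2.09 CPM (log2 fold change 5.26). Egf fell from 578 ± 165 to 17.8 ± 4.6 CPM (log2 fold change -5.02). Acadm, an enzyme of fatty acid oxidation, fell from 719 ± 103 to 166 ± 45.2 CPM (log2 fold change -2.12).

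Of 35 macrophage and monocyte genes 35 rose (median 2.90). Of 40 matrix and fibroblast genes 37 rose and 1 fell (median 2.19), with Fn1, the matrix protein fibronectin, at a log2 fold change of 3.06. Genes of failed proximal tubule repair rose at 16 of 16 members (median 2.32) and tubular injury genes at 27 of 32 (30 adjusted over the list alone, median 2.49). G2 and mitosis genes were higher than in Control at 45 of 50 members (median 2.12) and S phase genes at 34 of 46 (median 1.21). Of 14 T and NK cell genes 11 rose (12 adjusted over the list alone, median 1.98, adjusted p = 0.202 with an estimated correlation), among them the chemokine Ccl5, which rose from 3.6 ± 1.1 to 23.8 ± 10.6 CPM (log2 fold change 2.72). Of 21 YAP-TEAD targets 11 rose and 1 fell (median 0.95), and of 15 epithelial progenitor genes 8 rose and 1 fell (median 0.99).

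Among tubule and metabolic genes 43 of 45 proximal tubule, 29 of 32 fatty acid oxidation and 63 of 69 oxidative phosphorylation members fell, and 43, 30 and 65 did so when adjusted over the list alone (medians -2.02, -1.20 and -1.01). Ndufa10, a subunit of respiratory complex I, fell from 363 ± 65.1 to 139 ± 12.8 CPM (log2 fold change -1.39). Neutrophil genes kept a positive median of 3.97 (adjusted p = 0.141 with an estimated correlation), the p53 target list one of 0.36 (adjusted p = 0.0796 with an estimated correlation) and the ribosome biogenesis list one of 0.46 (adjusted p = 0.25 with an estimated correlation). The principal cell and cholesterol synthesis lists had medians of -0.80 (adjusted p = 0.14 with an estimated correlation) and -0.67 (adjusted p = 0.202 with an estimated correlation).

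Of 15701 genes 6218 changed in the edgeR test, 3371 higher and 2847 lower. Among them 3187 had groups that did not overlap, a count among genes already picked by the test. Camera called 22 of 34 lists, 14 higher and 8 lower, of which 16 held with an estimated correlation, and median, mean and test differed in sign for glycolysis and podocytes. UIRI d7 held no library in block 2b, so block 1a (3 against 3 libraries, 4443 genes changed) and the fit with the block as a covariate (6416 genes changed) compare these groups within blocks.

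The comparison of UIRI+Nx d7 with Control asks how far the injured kidney stood from an uninjured one when it was the only kidney from day 3 on. Arg1, an enzyme of alternatively activated macrophages, rose from 0.138 ± 0.166 to 55.9 ± 37.1 CPM (n = 6 and 6, log2 fold change 8.31, SE 0.74, edgeR adjusted p = 2.58e-09). Havcr1 rose from 4.32 ± 1.36 to 225 ± 111 CPM (log2 fold change 5.71, SE 0.43, edgeR adjusted p = 1.62e-10). Sox9 rose from 5.61 ± 1.24 to 157 ± 39.6 CPM (log2 fold change 4.80) and Col1a1 rose from 63.4 ± 14.8 to 821 ± 190 CPM (log2 fold change 3.69). Kap, the androgen-regulated protein of the proximal tubule, fell from 47500 ± 10000 to 1030 ± 348 CPM (log2 fold change -5.52, SE 0.47, edgeR adjusted p = 1.03e-09). Inmt, a methyltransferase, fell from 707 ± 42.5 to 6.82 ± 3.03 CPM (log2 fold change -6.68).

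Tubular injury genes rose at 30 of 32 members (median 2.63). Matrix and fibroblast genes rose at 38 of 40 with 1 lower (median 2.32), and G2 and mitosis genes at 46 of 50 with 1 lower (median 2.01). Of 25 p53 targets and cell cycle inhibitors 12 rose (14 adjusted over the list alone, median 0.58), and of 15 epithelial progenitor genes 8 rose and 2 fell (median 1.16). Proximal tubule genes fell at 33 of 45 members (37 adjusted over the list alone, median -1.49) and fatty acid oxidation genes at 20 of 32 (median -0.80). Oxidative phosphorylation genes fell at 34 of 69 (median -0.56, adjusted p = 0.108 with an estimated correlation). Of 14 T and NK cell genes 1 rose and 3 fell (median -0.81, camera adjusted p = 0.126), among them Trac, the constant part of the T cell receptor alpha chain, which fell from 4.55 ± 0.904 to 1.16 ± 1.01 CPM (log2 fold change -1.90). Of 25 interferon response genes 1 rose and 4 fell (median -0.37, camera adjusted p = 0.105).

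In UIRI+Nx d7 4909 of 15701 genes changed against Control in the edgeR test, 2709 higher and 2200 lower. Groups did not overlap in 2634 of them, a count among genes already picked by the test. Camera called 18 of 34 lists, 12 higher and 6 lower, and 15 held with an estimated correlation; signs of median, mean and test differed for glycolysis, B and plasma cells, cholesterol synthesis and the circadian clock. Within blocks 1a (3 against 3 libraries) and 2b (2 against 2) the counts were 2933 and 1709.

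The comparison of UIRI+Nx d7 with UIRI d7 asks what removing the other kidney on day 3 did to the injured kidney by day 7. Calb1 (ENSMUSG00000028222, chromosome 4, 15881264 to 15908064 in GRCm38) rose from 46.9 ± 11.5 to 361 ± 102 CPM (n = 6 and 6, log2 fold change 2.94, SE 0.28, edgeR adjusted p = 6.37e-07). Lyve1, a hyaluronan receptor of lymphatic vessels and of some macrophages, rose from 0.521 ± 0.314 to 8.53 ± 5.04 CPM (log2 fold change 3.96, SE 0.53, edgeR adjusted p = 3.82e-05). Nqo1, a quinone reductase controlled by NRF2, rose from 13.4 ± 4.63 to 74.6 ± 11.2 CPM (log2 fold change 2.48, SE 0.26, edgeR adjusted p = 1.57e-06). Vcam1 (ENSMUSG00000027962, chromosome 3, 116109949 to 116129688 in GRCm38) fell from 514 ± 140 to 161 ± 27.8 CPM (log2 fold change -1.68, SE 0.22, edgeR adjusted p = 2.92e-05). Havcr1 fell from 677 ± 259 to 225 ± 111 CPM (log2 fold change -1.59, SE 0.35, edgeR adjusted p = 0.00668). Dnase1, a secreted nuclease of the tubule, fell from 78.2 ± 25 to 7.75 ± 5.59 CPM (log2 fold change -3.32, SE 0.34, edgeR adjusted p = 1.57e-06). The chemokine Ccl5 fell from 23.8 ± 10.6 to 3.71 ± 1.85 CPM (log2 fold change -2.66, SE 0.34, edgeR adjusted p = 2.15e-05).

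Lymphocyte genes fell with nephrectomy. Of 14 T and NK cell genes 10 fell (14 adjusted over the list alone, median -2.60), among them Cd4, which fell from 2.48 ± 0.657 to 0.207 ± 0.2 CPM (log2 fold change -3.68). Of 26 cytokine and chemokine genes 6 fell (13 adjusted over the list alone, where 2 rose, median -0.85). Cxcl9, a chemokine induced by interferon gamma, fell from 13.8 ± 15.5 to 0.957 ± 2.03 CPM (log2 fold change -3.79, SE 0.87, edgeR adjusted p = 0.00814). Of 25 interferon response genes 9 fell (19 adjusted over the list alone, median -0.90, adjusted p = 0.0526 with an estimated correlation), among them Rtp4, which fell from 28.6 ± 5.76 to 13.6 ± 2.21 CPM (log2 fold change -1.07). Macrophage and monocyte genes fell at 11 of 35 members and rose at 1 (median -0.60, adjusted p = 0.084 with an estimated correlation), with H2-Eb1, a class II antigen presentation chain, falling from 400 ± 152 to 76.2 ± 40.8 CPM while Arg1 rose from 8.33 ± 4.23 to 55.9 ± 37.1 CPM (log2 fold change 2.76). The B and plasma cell list had 2 of 7 genes lower (median -0.75, adjusted p = 0.0526 with an estimated correlation).

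Genes of failed proximal tubule repair fell at 6 of 16 members (9 adjusted over the list alone, median -0.77), with Relb, a subunit of NF-kappaB, falling from 40.5 ± 11.5 to 17.4 ± 2.08 CPM. NRF2 targets rose at 7 of 20 (12 adjusted over the list alone, median 0.61). Fatty acid oxidation genes rose at 7 of 32 (8 adjusted over the list alone, median 0.50), among them Acsl1, which rose from 93.7 ± 21.3 to 218 ± 49.7 CPM (log2 fold change 1.22). Oxidative phosphorylation genes rose at 8 of 69 (25 adjusted over the list alone, median 0.46, adjusted p = 0.0642 with an estimated correlation). Proximal tubule genes rose at 9 of 45 and fell at 2 (15 and 4 adjusted over the list alone, median 0.37, adjusted p = 0.258 with an estimated correlation), with G6pc, an enzyme of glucose release, rising from 27.2 ± 5.57 to 138 ± 75.9 CPM and Kap falling from 5550 ± 3800 to 1030 ± 348 CPM. Distal convoluted and connecting tubule genes rose at 3 of 12 (median 0.43), among them Klk1, which rose from 308 ± 126 to 1090 ± 113 CPM (log2 fold change 1.82). The loop of Henle and principal cell lists had medians of 0.45 and 0.72 (adjusted p = 0.0526 and 0.151 with an estimated correlation). Cholesterol synthesis genes rose at 5 of 25 (8 adjusted over the list alone, median 0.35, adjusted p = 0.135 with an estimated correlation), among them Insig1, a sensor of sterols, which rose from 15.4 ± 5.31 to 44.9 ± 9.33 CPM (log2 fold change 1.54).

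Proliferation, progenitor and matrix genes did not separate these groups as lists. Median log2 fold changes (camera adjusted p in brackets) were -0.14 for S phase (0.189) and -0.04 for G2 and mitosis (0.474). They were -0.06 for epithelial progenitors (0.919), -0.03 for YAP-TEAD targets (0.199) and 0.04 for matrix and fibroblast genes (0.569). Mki67, present in cycling cells, measured 10.5 ± 4.17 against 11.7 ± 5.73 CPM (log2 fold change -0.15, SE 0.33, edgeR adjusted p = 0.854), while Top2a fell from 92.8 ± 28.5 to 53.4 ± 19.3 CPM (log2 fold change -0.80, SE 0.24, edgeR adjusted p = 0.0392). Lcn2, a secreted marker of tubular injury, measured 235 ± 133 against 114 ± 57.7 CPM (log2 fold change 1.04, SE 0.49, edgeR adjusted p = 0.218). Of 25 p53 targets and cell cycle inhibitors 4 rose (median 0.31, adjusted p = 0.135 with an estimated correlation). The red blood cell and circadian clock lists had medians of -1.38 and 0.15 (adjusted p = 0.276 and 0.28 with an estimated correlation).

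With nephrectomy 1040 of 15701 genes changed in the edgeR test, 497 higher and 543 lower. Of these 401 had groups that did not overlap, a count among genes already picked by the test. Camera called 17 of 34 lists, 10 higher and 7 lower, and 6 held with an estimated correlation; the signs of median, mean and test differed for glycolysis and epithelial progenitors. The mitochondrial share of counts was higher in UIRI+Nx d7 than in UIRI d7 (4.62% against 2.77%, two-sided exact permutation p = 0.00649, n = 6 per group, adjusted p = 0.0476). In a fit of only the 2 groups 586 genes changed, with the library block as a covariate 1359 did, and within block 1a (3 against 3 libraries) 131 did.

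**Figure D3:**
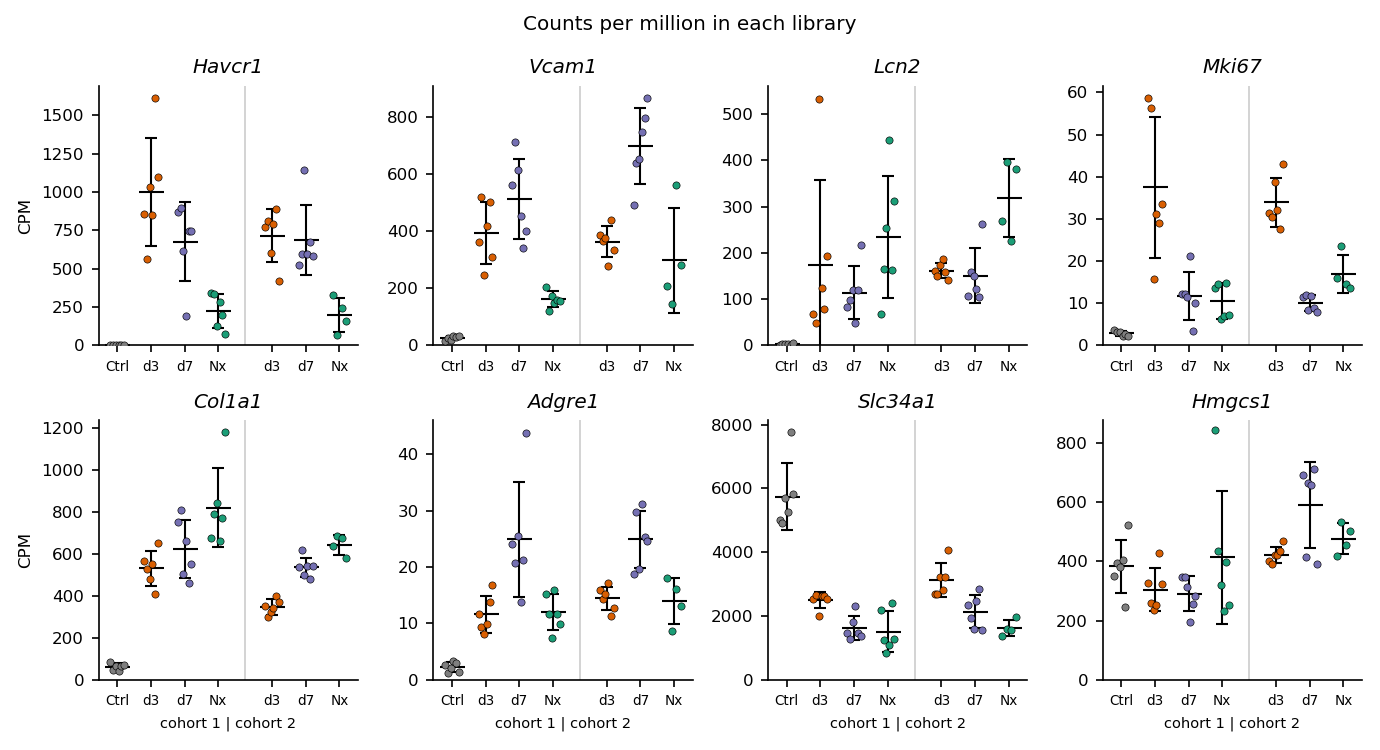
CPM (vertical axes, starting at 0) of 8 genes in each library (points) of each group (horizontal axes) in both cohorts, with bars for the mean ± SD. Havcr1 falls from a mean of 677 CPM in UIRI d7 to 225 CPM in UIRI+Nx d7 of the first cohort, while Mki67 lies at 11.7 and 10.5 CPM.

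The comparison of UIRI d7 with UIRI d3 asks what changed between the days of harvest with the other kidney in place. Tk1, a thymidine kinase of S phase, fell from 22.2 ± 3.65 to 5.1 ± 1.18 CPM (n = 6 and 6, log2 fold change -2.11, SE 0.22, edgeR adjusted p = 6.06e-06). Rrm2, a subunit of the reductase that makes deoxynucleotides, fell from 52.5 ± 13.5 to 12.6 ± 4.95 CPM (log2 fold change -2.07, SE 0.31, edgeR adjusted p = 0.000304). Mki67 fell from 37.4 ± 16.8 to 11.7 ± 5.73 CPM (log2 fold change -1.68, SE 0.33, edgeR adjusted p = 0.00514). Ccl8, a chemokine for monocytes, rose from 3.77 ± 2.5 to 35.6 ± 24 CPM (log2 fold change 3.23, SE 0.58, edgeR adjusted p = 0.0017). Stra6, a receptor for the retinol carrier protein, rose from 6.85 ± 2.03 to 39.2 ± 10.5 CPM (log2 fold change 2.52, SE 0.31, edgeR adjusted p = 4.48e-05).

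Of 50 G2 and mitosis genes 37 fell (48 adjusted over the list alone, median -1.51). Of 46 S phase genes 19 fell (42 adjusted over the list alone, median -1.05). Kif23, a motor of cell division, fell from 50.5 ± 6.12 to 16 ± 5.12 CPM (log2 fold change -1.66). Macrophage and monocyte genes rose at 17 of 35 members (26 adjusted over the list alone, median 1.07), among them Lyz2, which rose from 203 ± 77.8 to 603 ± 188 CPM (log2 fold change 1.57). T and NK cell genes rose at 5 of 14 (8 adjusted over the list alone, median 1.36), among them Cd3d, which rose from 0.963 ± 0.64 to 4.89 ± 2.05 CPM (log2 fold change 2.29). Matrix and fibroblast genes rose at 5 of 40 and fell at 1 (median 0.35), with Col12a1, a fibril-associated collagen, rising from 12.7 ± 5.02 to 44.1 ± 18.8 CPM. The failed repair list had 2 of 16 genes higher (median 0.41). Tubular injury genes fell at 4 of 32 and rose at 1 (median -0.32, adjusted p = 0.116 with an estimated correlation), with S100a6, a calcium-binding protein, falling from 4030 ± 801 to 1470 ± 342 CPM. Havcr1 measured 677 ± 259 against 1000 ± 352 CPM (log2 fold change -0.57, SE 0.35, edgeR adjusted p = 0.52). The proximal tubule list had 3 of 45 genes lower and 1 higher (median -0.49, adjusted p = 0.116 with an estimated correlation).

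From day 3 to day 7 the edgeR test called 409 of 15701 genes, 195 higher and 214 lower. Of these 247 had groups that did not overlap, a count among genes already picked by the test. Camera called 20 of 34 lists, 9 higher and 11 lower, and 6 held with an estimated correlation; the signs of median, mean and test differed for p53 targets, the distal convoluted and connecting tubule and adipocytes. Within block 1a (3 against 2 libraries) the edgeR test called 0 of 16351 genes, with 1676 at an unadjusted p under 0.05, and no other tool was run within blocks. Over all libraries DESeq2 called 711 genes and limma voom 1006, and edgeR called 247 without UIRI d7 replicate 3 and 263 without UIRI d7 replicate 2. The mitochondrial share of counts was lower on day 7 (2.77% against 4.22%, two-sided exact permutation p = 0.00866, n = 6 per group, smallest possible 0.00216, adjusted p = 0.0476). The hemoglobin share was 0.061% against 0.0137% (two-sided exact permutation p = 0.0303, smallest possible 0.00216, adjusted p = 0.124), and the red blood cell list had a median of 1.995 with 0 of 7 genes called (camera adjusted p = 0.0245, adjusted p = 0.419 with an estimated correlation).

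The comparison of UIRI+Nx d7 with UIRI d3 asks how the kidney that lost its partner on day 3 had changed 4 days later. Calb1 rose from 35.9 ± 18.3 to 361 ± 102 CPM (n = 6 and 6, log2 fold change 3.33, SE 0.29, edgeR adjusted p = 1.26e-07). Cd163, a scavenger receptor of macrophages, rose from 3.93 ± 1.09 to 40.7 ± 31.1 CPM (log2 fold change 3.37, SE 0.50, edgeR adjusted p = 0.000128). Havcr1 fell from 1000 ± 352 to 225 ± 111 CPM (log2 fold change -2.15, SE 0.36, edgeR adjusted p = 0.000431). Top2a fell from 233 ± 67.9 to 53.4 ± 19.3 CPM (log2 fold change -2.12, SE 0.24, edgeR adjusted p = 8.48e-06). Dnase1 (ENSMUSG00000005980, chromosome 16, 4036942 to 4040024 in GRCm38) fell from 122 ± 25.4 to 7.75 ± 5.59 CPM (log2 fold change -3.96, SE 0.35, edgeR adjusted p = 1.26e-07).

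Of 50 G2 and mitosis genes 42 fell (46 adjusted over the list alone, median -1.57). Of 46 S phase genes 32 fell (44 adjusted over the list alone, median -1.17), with Mcm3 at a log2 fold change of -1.51. Matrix and fibroblast genes rose at 8 of 40 and fell at 1 (median 0.44), with Fn1 rising from 218 ± 40.3 to 424 ± 86.5 CPM. NRF2 targets rose at 4 of 20 (median 0.31), among them the reductase Cbr3, which rose from 5.33 ± 1.48 to 25.8 ± 7.52 CPM (log2 fold change 2.27), and distal convoluted and connecting tubule genes at 3 of 12 (median 0.35). Ribosome biogenesis and Myc genes fell at 2 of 30 (8 adjusted over the list alone, median -0.36). T and NK cell genes fell at 2 of 14 (6 adjusted over the list alone, median -1.26, adjusted p = 0.092 with an estimated correlation), and interferon response genes at 4 of 25 (median -0.63, adjusted p = 0.122 with an estimated correlation). Neutrophil genes fell at 3 of 9 (median -2.30, adjusted p = 0.346 with an estimated correlation), among them S100a9, a calprotectin subunit whose UIRI d3 values had a mean of 114 and an SD of 201 CPM.

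By the edgeR test 805 of 15701 genes changed, 324 higher and 481 lower. In 427 of them the groups did not overlap, a count among genes already picked by the test. Camera called 20 of 34 lists, 11 higher and 9 lower, of which 6 held with an estimated correlation, with signs that differed for the proximal tubule and red blood cell lists. Limma voom called 1584 genes, edgeR called 524 without UIRI+Nx d7 replicate 4 and 525 without replicate 3 of that group, and the edgeR test within blocks 1a (3 against 2 libraries) and 2b (2 against 3) called 113 and 37.

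Injury and nephrectomy effects were set against each other over the genes called in UIRI d7 against Control. Of these 6218 genes, 77.3% had a log2 fold change of the opposite sign in UIRI+Nx d7 against UIRI d7, and the correlation across genes, which are not independent replicates, was -0.46 (Spearman's rho -0.539). Among genes higher after injury r was -0.171, and among genes lower it was -0.0339. The UIRI d7 libraries enter both fold changes. In simulated unchanged groups that shared them, r over all genes was -0.502 (SD 0.00987, 10 simulations) with 66.7% of signs opposite and a covariance of -0.057. The observed values over all 15701 genes were -0.385, 67.9% and -0.256. The observed r was thus less negative than the simulated one, while the covariance differed from the simulated one by -0.199. With the UIRI d7 libraries split 3 and 3 between the 2 fold changes, r over the calls was -0.36 on average (-0.459 to -0.243 over 20 splits) and 70.5% of signs were opposite, while over all genes these were -0.259 and 60%. With the nephrectomy effect of the second cohort, which shares no library, r was -0.19 and 61.7% of signs were opposite over 6087 genes called after injury, and -0.161 and 56% over all 15263 genes.

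By calls, 377 genes rose with injury and fell with nephrectomy, and 360 fell with injury and rose with nephrectomy. In the same direction 24 genes rose in both and 39 fell in both. The shared UIRI d7 libraries favour opposite calls, so no count for unchanged groups is given beside them. Calb1 fell after injury and rose with nephrectomy, while Havcr1, Vcam1 and Cd44 rose after injury and fell with nephrectomy. Egf fell after injury (log2 fold change -5.02) and did not change with nephrectomy. With the second cohort's nephrectomy calls, which share no library with the injury calls, the opposite counts were 220, against 88.2 for independent lists, and 173, against 72.1. The counts in the same direction were 70 higher in both, against 87.4 for independent lists, and 80 lower in both, against 72.9.

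In the second cohort UIRI+Nx d7 (n = 4) was compared with UIRI d7 (n = 6) to ask whether the nephrectomy effect appeared in a separate set of libraries. Calb1 rose from 16.4 ± 7.57 to 188 ± 79.5 CPM (n = 6 and 4, log2 fold change 3.54, SE 0.28, edgeR adjusted p = 6.59e-07). Slc38a3, a glutamine transporter, rose from 11.1 ± 4.1 to 74.9 ± 30.7 CPM (log2 fold change 2.75). Gdf15, a stress-induced cytokine, rose from 335 ± 94.7 to 1020 ± 266 CPM (log2 fold change 1.61). Havcr1 fell from 685 ± 229 to 198 ± 113 CPM (log2 fold change -1.79, SE 0.34, edgeR adjusted p = 0.00372). Vcam1 fell from 698 ± 132 to 298 ± 184 CPM (log2 fold change -1.23, SE 0.27, edgeR adjusted p = 0.0115). Dnase1 fell from 128 ± 29.5 to 13.6 ± 5.83 CPM (log2 fold change -3.26). Cxcl10, a chemokine induced by interferons, fell from 39.9 ± 11.8 to 7.29 ± 6.82 CPM (log2 fold change -2.44). These adjusted p are from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

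Of 15 measured T and NK cell genes 8 fell (13 adjusted over the list alone, median -2.01), among them Cd3d, which fell from 2.99 ± 1.21 to 0.218 ± 0.0748 CPM (log2 fold change -3.81). Failed repair genes fell at 6 of 16 (8 adjusted over the list alone, median -0.57), and distal convoluted and connecting tubule genes rose at 4 of 11 (6 adjusted over the list alone, median 0.50). NRF2 targets rose at 5 of 20 (median 0.31, adjusted p = 0.0518 with an estimated correlation) and fatty acid oxidation genes at 6 of 31 (median 0.30, adjusted p = 0.176 with an estimated correlation). G2 and mitosis genes rose at 5 of 50 (8 adjusted over the list alone, median 0.29, adjusted p = 0.196 with an estimated correlation), with Mki67 rising from 10 ± 1.84 to 16.9 ± 4.5 CPM and Cdkn1a from 83.1 ± 14.9 to 141 ± 24.6 CPM. Proximal tubule genes fell at 8 of 45 and rose at 5 (median -0.27, adjusted p = 0.475 with an estimated correlation), among them Slc7a13, a transporter of the straight segment, which fell from 72.3 ± 26.8 to 5.7 ± 3.7 CPM (log2 fold change -3.67). Macrophage and monocyte genes fell at 9 of 35 and rose at 1 (median -0.46, adjusted p = 0.0708 with an estimated correlation), and cytokine and chemokine genes fell at 7 of 26 (median -0.53, adjusted p = 0.0518 with an estimated correlation). The list median of the red blood cell genes was -1.33 (adjusted p = 0.198 with an estimated correlation), beside a hemoglobin share of counts of 0.00391% against 0.0112% (two-sided exact permutation p = 0.00952, n = 4 and 6, smallest possible 0.00476, adjusted p = 0.0476). The mitochondrial share was 3.95% against 2.82% (two-sided exact permutation p = 0.0286, smallest possible 0.00476, adjusted p = 0.124).

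In this cohort the edgeR test called 814 of 15543 genes, 401 higher and 413 lower. Among them 553 had groups that did not overlap, a count among genes already picked by the test. By chance 4 against 6 libraries give this for 0.952% of genes that no test has picked. Camera called 17 of 34 lists, 8 higher and 9 lower, and 3 held with an estimated correlation; signs differed for the neutrophil, ribosome biogenesis and adrenal cortex lists. Without UIRI+Nx d7 replicate 2 of this cohort 328 genes were called, and within blocks 2a (2 against 2 libraries) and 2c (2 against 4) 176 and 16 were.

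The log2 fold changes of the nephrectomy comparison correlated at r = 0.509 between the cohorts over 15263 genes, of which 59.2% had the same sign. Of 1024 genes called in the first cohort 945 (92.3%) had the same sign in the second, or 1229 of 1342 (91.6%) with the library block as a covariate. Both cohorts called 297 genes, all with the same sign, 128 higher and 169 lower, where independent lists would share 12.9 and 14.1. In a joint edgeR fit no gene differed between the cohorts in this comparison (0 of 16606, with 1411 at an unadjusted p under 0.05, no other tool having been run for this test).

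Of the 34 lists 9 differed between the cohorts in the joint fit in camera with the preset correlation and 0 with an estimated one. The proximal tubule list had medians of 0.37 in the first and -0.27 in the second cohort (camera adjusted p = 2.02e-08, adjusted p = 0.251 with an estimated correlation). The G2 and mitosis list had medians of -0.04 and 0.31 (camera adjusted p = 2.21e-05, adjusted p = 0.545 with an estimated correlation). S phase genes had -0.14 and 0.12 (camera adjusted p = 0.00551, adjusted p = 0.545 with an estimated correlation) and podocyte genes -0.36 and 0.12 (camera adjusted p = 0.0325, adjusted p = 0.251 with an estimated correlation). For 5 lists both medians had the same sign. They were oxidative phosphorylation (0.46 and 0.11, camera adjusted p = 7.64e-09, adjusted p = 0.368 with an estimated correlation), NRF2 targets (0.62 and 0.35, camera adjusted p = 0.00163, adjusted p = 0.251 with an estimated correlation) and the interferon response (-0.90 and -0.34, camera adjusted p = 0.000604, adjusted p = 0.545 with an estimated correlation). The others were the loop of Henle (0.44 and 0.14, camera adjusted p = 0.00736, adjusted p = 0.368 with an estimated correlation) and cholesterol synthesis (0.35 and 0.16, camera adjusted p = 0.00821, adjusted p = 0.545 with an estimated correlation).

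**Figure D4:**
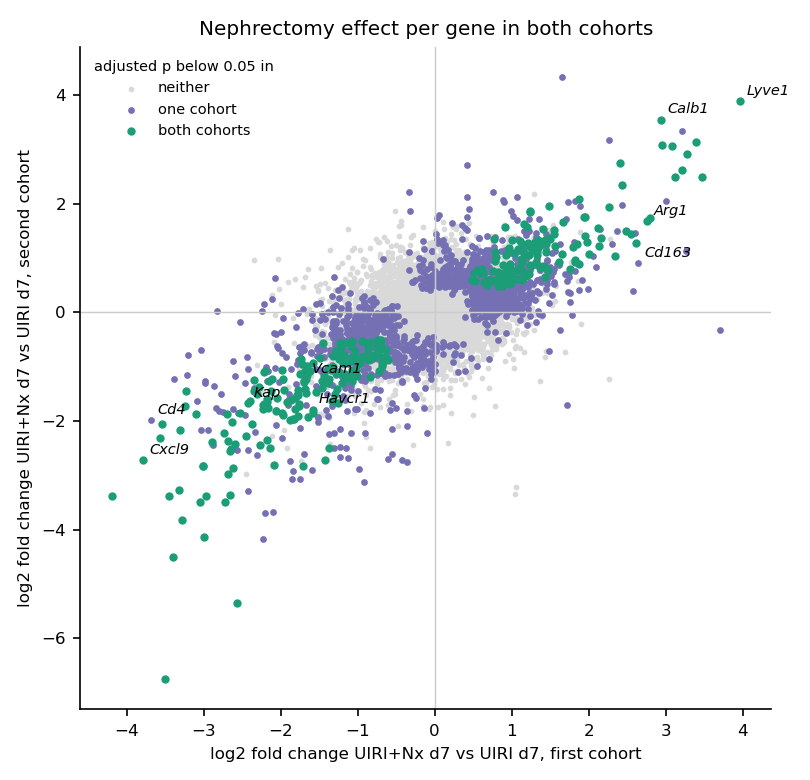
Log2 fold change of UIRI+Nx d7 against UIRI d7 in the first cohort (horizontal axis) and in the second (vertical axis), with a point per gene coloured by whether the gene was called in neither, either or both cohorts. The 297 genes called in both lie in the upper right (128) and the lower left (169), with Calb1 at 2.94 and 3.54 and Vcam1 at -1.68 and -1.23.

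The second cohort's comparison of UIRI d7 with UIRI d3 (n = 6 each) repeats the question of change between the harvest days. Rrm2 fell from 50.8 ± 9.9 to 12.2 ± 1.91 CPM (n = 6 and 6, log2 fold change -2.06, SE 0.16, edgeR adjusted p = 2.23e-07). Mki67 fell from 33.9 ± 5.79 to 10 ± 1.84 CPM (log2 fold change -1.74). Ube2c, an enzyme of mitotic exit, fell from 45 ± 3.53 to 12.8 ± 1.27 CPM (log2 fold change -1.80). Stra6 rose from 3.79 ± 1.45 to 35.1 ± 10.1 CPM (log2 fold change 3.21) and Ccl8 rose from 9.1 ± 2.35 to 82.2 ± 29.7 CPM (log2 fold change 3.17). Vcam1 rose from 364 ± 53.4 to 698 ± 132 CPM (log2 fold change 0.94, SE 0.24, edgeR adjusted p = 0.0166). Hba-a2, a hemoglobin chain whose reads cannot be told from those of a near-identical copy with certainty, fell from 37.7 ± 12.8 to 7.64 ± 2.96 CPM (log2 fold change -2.27). Aqp2, the water channel of principal cells, fell from 276 ± 106 to 82.4 ± 35.7 CPM (log2 fold change -1.75).

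G2 and mitosis genes fell at 46 of 50 members (median -1.37) and S phase genes at 35 of 46 (median -0.96). Macrophage and monocyte genes rose at 23 of 35 (median 0.86), matrix and fibroblast genes at 16 of 40 with 2 lower (median 0.43), cytokine and chemokine genes at 10 of 26 with 1 lower (median 0.75), and failed repair genes at 6 of 16 (median 0.54). Adjusted over the list alone these lists had 48, 43, 25, 19, 15 and 8 genes changed in those directions. T and NK cell genes rose at 4 of 15 (median 1.21, adjusted p = 0.0627 with an estimated correlation), and with the library block as a covariate that median was 0.35. Red blood cell genes fell at 5 of 7 (median -2.00, adjusted p = 0.0627 with an estimated correlation), and principal cell genes at 3 of 12 (median -0.60, adjusted p = 0.0627 with an estimated correlation). The hemoglobin share of counts was 0.0112% against 0.0472% and the mitochondrial share 2.82% against 4.37% (n = 6 each, two-sided exact permutation p = 0.00216 for each, the smallest possible, adjusted p = 0.0194).

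A total of 1330 of 15543 genes changed in the edgeR test, 701 higher and 629 lower. Among them 707 had groups that did not overlap, a count among genes already picked by the test. With the library block as a covariate 349 genes were called, and within block 2a (2 against 6 libraries) 207, since UIRI d3 held no library in block 2c. Camera called 18 of 34 lists, 7 higher and 11 lower, with 6 held at an estimated correlation and signs that differed for podocytes, endothelium and the circadian clock. Of 408 genes called in the first cohort 402 (98.5%) had the same sign here, 382 of 389 with the block, beside 69.5% of all 15263 genes. A total of 300 were called in both cohorts, 135 higher and 165 lower, where independent lists would share 8.85 and 8.72. The joint fit found a difference between cohorts in 0 of 16606 genes (edgeR, 484 at an unadjusted p under 0.05, no other tool run). As lists, the red blood cell genes (adjusted p = 0.0313 with an estimated correlation) and the principal cell genes (adjusted p = 0.0317 with an estimated correlation) differed between cohorts in this comparison, and the preset correlation gave 14 of 34 lists.

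UIRI+Nx d7 (n = 4) was also compared with UIRI d3 (n = 6) in the second cohort. Calb1 rose from 23 ± 3.83 to 188 ± 79.5 CPM (n = 6 and 4, log2 fold change 3.03, SE 0.27, edgeR adjusted p = 8.91e-07). Gpnmb, a glycoprotein of phagocytes, rose from 27.4 ± 4.93 to 108 ± 29.1 CPM (log2 fold change 1.98). Kap fell from 12300 ± 1930 to 2520 ± 604 CPM (log2 fold change -2.29) and Havcr1 fell from 714 ± 173 to 198 ± 113 CPM (log2 fold change -1.85). Umod, an abundant protein of normal urine, fell from 1280 ± 128 to 609 ± 50.1 CPM (log2 fold change -1.08).

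G2 and mitosis genes fell at 38 of 50 members (median -1.05) and S phase genes at 23 of 46 (median -0.90), and 46 and 35 fell when adjusted over the list alone. Matrix and fibroblast genes rose at 15 of 40 (median 0.51), among them Col12a1, with a log2 fold change of 2.38, and distal convoluted and connecting tubule genes at 4 of 11 (median 0.45). Red blood cell genes fell at 5 of 7 (median -3.44), beside a hemoglobin share of counts of 0.00391% against 0.0472% (two-sided exact permutation p = 0.00952, n = 4 and 6, smallest possible 0.00476, adjusted p = 0.0476). Proximal tubule genes fell at 17 of 45 and rose at 1 (median -0.46, adjusted p = 0.104 with an estimated correlation).

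Here 935 of 15543 genes changed in the edgeR test, 462 higher and 473 lower. Groups did not overlap in 692 of them, a count among genes already picked by the test. Camera called 12 of 34 lists, 4 higher and 8 lower, and 5 held with an estimated correlation; signs differed for glycolysis, failed repair, cytokines and the circadian clock. Without UIRI+Nx d7 replicate 2 of this cohort 554 genes were called, without replicate 4 there were 615, and within block 2a (2 against 6 libraries) there were 477. Of 799 genes called in the first cohort 758 (94.9%) had the same sign here, beside 60.7% of all 15263 genes, and 323 were called in both, where independent lists would share 9.6 higher and 14.7 lower, against 143 and 180 observed. The joint fit called 0 of 16606 genes as different between cohorts (edgeR, 1115 at an unadjusted p under 0.05, no other tool run), and camera 17 of 34 lists with the preset correlation and 0 with an estimated one.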

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

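All tests weighed in this part, including the splits, the comparisons between cohorts and the tests of the library block, were chosen after the results they address had been seen. Of 231 groups of values examined, of marker genes and of library quality measures, 19 held a library far from the rest by a Dixon test for single outliers. All of these were marker values. Over all groups chance gives about 1 in 20, or 11.6, if values are normally distributed.

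In Control, replicate 5 had Slc34a1 at 7780 CPM (the other 5 libraries 4910 to 5810) and Havcr1 at 1.69 CPM (4.32 to 5.35). UIRI d3 replicate 3 had Slc34a1 at 2010 CPM (2520 to 2670), Aqp2 at 786 (118 to 231) and Lcn2 at 534 (47.4 to 193), and UIRI d3 replicate 6 had Umod at 2470 (1140 to 1430). UIRI d7 replicate 4 had Pax2 at 132 CPM (30.8 to 58.7) and replicate 5 had Acta2 at 521 (171 to 271). UIRI+Nx d7 replicate 6 had Col1a1 at 1180 CPM (661 to 843) and Tgfb1 at 25.4 (11.6 to 16.4). Replicate 2 of that group had Ccn1 at 469 (4.07 to 81.3) and Ccl2 at 44.3 (10.6 to 19.4), and replicate 1 had Hmgcs1 at 844 (233 to 437). In the second cohort UIRI d7 replicate 3 had Cdk1 at 46.8 CPM (16.1 to 23.5) and Havcr1 at 1140 (523 to 675), and replicate 6 had Lcn2 at 262 (105 to 159). UIRI d3 replicate 4 of that cohort had Ccn2 at 557 (6.77 to 187), replicate 6 had Egf at 16.2 (26.9 to 29.7) and replicate 1 had Acta2 at 423 (245 to 298).

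Between day 3 and day 7 the cohorts differed in the red blood cell list (adjusted p = 0.0313 with an estimated correlation, medians 1.99 in the first and -2.02 in the second cohort) and in the principal cell list (adjusted p = 0.0317, medians -0.05 and -0.62), in the joint edgeR fit. The use of the estimated correlation here was decided after seeing that the preset one would list 14 of 34 lists for UIRI d7 against UIRI d3, 9 for UIRI+Nx d7 against UIRI d7 and 17 for UIRI+Nx d7 against UIRI d3. With the estimated correlation these numbers were 2, 0 and 0.

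The column of no group held Havcr1 at 559 CPM (6959 counts, exact Poisson 95% interval 546 to 572). This lay above the 1.34 to 4.89 CPM of the 6 Control libraries and within the span of the injured groups. On the TMM scale their means were 1000 (UIRI d3), 677 (UIRI d7) and 225 (UIRI+Nx d7) in the first cohort and 714, 685 and 198 in the second. Its column is named as undetermined, a usual name for reads that were assigned to no library, and its label gives no group, so its values are set beside those of the groups without a test.

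For each comparison the real groups were set among 100 splits of the same libraries in fits of the 2 groups alone, and only 1 of them, the real one, gave as many genes. A share of 1 in 100 per comparison, unadjusted over the comparisons, argues against chance alone but does not exclude it. The splits were drawn without regard to the library block, so they cannot tell the groups from the block. The counts for UIRI d3, UIRI d7 and UIRI+Nx d7 against Control were 5046 genes (highest other split 401), 5404 (1402) and 4679 (700). They were 586 for UIRI+Nx d7 against UIRI d7 (highest other 71) and 325 for UIRI d7 against UIRI d3 (highest other 1). For UIRI+Nx d7 against UIRI d3 the count was 727 (highest other 1). Within the second cohort the counts were 553 for UIRI+Nx d7 against UIRI d7 (highest other 311) and 1565 for UIRI d7 against UIRI d3 (highest other 1213). For its UIRI+Nx d7 against UIRI d3 the count was 727 (highest other 5). UIRI d3 of this cohort had no library in block 2c, so its real splits partly follow the block. The splits with 1402 and 1213 genes each exchanged a single library between the real groups. The split with 311 exchanged 2 of the 4 UIRI+Nx d7 libraries, with 2 libraries from each of blocks 2a and 2c as in the real group, so nearness to the real groups does not cover it and its cause was not tested.

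T and NK cell genes were lower with nephrectomy in both cohorts, with list medians of -2.60 and -2.01. With the library block as a covariate the members' fold changes rose by a median of -0.1207 in the first and 0.0737 in the second cohort, and the upper quartiles of the members were -1.9884 and -1.8025, which argues against the block as the source. The macrophage and monocyte list fell less, with medians of -0.5983 and -0.4551 and lower quartiles of -1.34 and -0.80 that lie above the upper quartiles of the T and NK cell members (-1.76 and -1.85), which argues against a lower share of all leukocytes. The red blood cell list also had medians below 0, -1.38 and -1.33 (adjusted p = 0.276 and 0.198 with an estimated correlation). The hemoglobin share of counts was 0.0179% against 0.061% in the first (two-sided exact permutation p = 0.136, adjusted p = 0.322) and 0.00391% against 0.0112% in the second cohort (p = 0.00952, adjusted p = 0.0476). Less blood in the samples was not tested as the source and stays open. A lower number of T and NK cells after nephrectomy is a candidate explanation that stays open as a hypothesis, as does lower expression per cell.

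Genes known as male-biased in the kidney, a list made after values had been seen, were lower with nephrectomy, with medians of -0.56 in the first (4 of 18 genes fell, camera adjusted p = 0.000331 in limma, adjusted p = 0.186 with an estimated correlation) and -0.95 in the second cohort (8 of 18 fell, adjusted p = 1.45e-12, and 0.0109 with an estimated correlation). The block was first tested by the members' upper quartiles with the block (0.0356 and -0.1891), which left it undecided, and then by the members' rise with the block, whose medians of -0.0101 and 0.0086 argue against it. The proximal tubule list without shared members had medians of 0.4569 and -0.2278, with lower quartiles of 0.07 and -0.45 above the male-biased medians. In the first cohort its lower quartile of 0.0737 also lay just above the male-biased upper quartile of 0.0723. This argues against a lower share of proximal tubule RNA in that cohort. In the second the quartiles overlapped (-0.448 to 0.273 against -1.83 to -0.262), so there it stays open. A lower share of a single tubule segment was not tested. A lower androgen response may underlie the pattern, but the first cohort's call is lost with an estimated correlation and hormone levels were not measured in the data used here.

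The count for UIRI d7 against UIRI d3 in the second cohort dropped from 1330 to 349 genes with the library block as a covariate. The log2 fold changes of the 1330 genes kept their signs, with a slope of 0.903 between the fits, which argues against the block as the whole of the fold changes. The median ratio of fold changes was 0.869 (quartiles 0.691 and 1.01), and that of standard errors was 1.19 (quartiles 1.13 and 1.24). The larger standard error is a candidate explanation for the lost calls, beside smaller folds. UIRI d3 had no library in block 2c, so the part of the effect that lies in that block cannot be told apart from the day.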

How the results depend on the processing

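The tests by library block, with the second cohort's nephrectomy effect, without libraries that stand apart, without Gm42418 and, for lists, without single libraries were chosen after the results had been seen; the other alternatives were chosen before the data were examined. Over all alternatives 34639 of 36924 values of named genes kept their side of the threshold, 1742 lost and 542 gained a call and 1 reversed. For lists these were 5418 of 5710, 197, 91 and 4. A change of sign counted as a reversal only where either fit passed the threshold, so values kept without a call may have changed sign. Counts of genes within 1.5 times the reported ones ran from 4943 to 6650 (UIRI d3 against Control), 4443 to 7208 (UIRI d7 against Control), 4621 to 5812 (UIRI+Nx d7 against Control), 766 to 1503 (UIRI+Nx d7 against UIRI d7), 305 to 415 (UIRI d7 against UIRI d3) and 701 to 1171 (UIRI+Nx d7 against UIRI d3), and in the second cohort from 553 to 1203, 1163 to 1802 and 727 to 1330 for the last 3. With the replicate number as a block the counts in this order were 5180, 6225, 4827, 963, 367, 756, 796, 1463 and 1185.

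Within a library block, with fewer samples, counts were 2729 (1a) and 2366 (2b) for UIRI d3 against Control, 2933 and 1709 for UIRI+Nx d7 against Control, 131 (1a) for UIRI+Nx d7 against UIRI d7, 113 and 37 for UIRI+Nx d7 against UIRI d3, and 0 of 16351 by edgeR (1676 at an unadjusted p under 0.05; no other tool run) for UIRI d7 against UIRI d3 in block 1a. The second cohort gave 176 (2a) and 16 (2c) for UIRI+Nx d7 against UIRI d7, 207 (2a) for UIRI d7 against UIRI d3, 349 with the block as a covariate, and 477 (2a) for UIRI+Nx d7 against UIRI d3. For these and the following the cause was not tested unless named. Fitting only the 2 groups gave 586 for UIRI+Nx d7 against UIRI d7. DESeq2 gave 711 and voom 1006 for UIRI d7 against UIRI d3, and voom 1584 for UIRI+Nx d7 against UIRI d3, 2849 for UIRI d7 against UIRI d3 of the second cohort and 1558 for its UIRI+Nx d7 against UIRI d3. With an estimated correlation the lists called were 6, 6 and 6 for UIRI+Nx d7 against UIRI d7, UIRI d7 against UIRI d3 and UIRI+Nx d7 against UIRI d3, and 3, 6 and 5 in the second cohort. The reversal r of -0.46 was -0.385 over all genes, -0.19 with the second cohort and -0.36 with divided libraries, and its 77.3% was 67.9, 61.7 and 70.5. The same-sign share of UIRI+Nx d7 against UIRI d3 between cohorts was 92.8% with the block.

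Leaving out each library gave 4634 to 5081, 5709 to 6277 and 4451 to 4940 genes against Control, 695 to 1087 for UIRI+Nx d7 against UIRI d7, 247 (without UIRI d7 replicate 3; 263 without replicate 2) to 405 for UIRI d7 against UIRI d3, and 524 (without UIRI+Nx d7 replicate 4; 525 without replicate 3) to 914 for UIRI+Nx d7 against UIRI d3. The second cohort gave 328 (without UIRI+Nx d7 replicate 2) to 898, 923 to 1536, and 554 (without UIRI+Nx d7 replicate 2; 615 without replicate 4) to 1147. Lists called stayed between 11 and 22. Lists not called over all libraries were called in the opposite direction in single settings (camera adjusted p from limma in brackets): urothelium for UIRI d3 against Control in block 1a (0.0454) and for UIRI+Nx d7 against UIRI d3 in block 2b (0.002615), adipocytes for UIRI d7 against UIRI d3 in block 1a (0.005282), and the interferon response for UIRI+Nx d7 against UIRI d3 of the second cohort without UIRI+Nx d7 replicate 3 (0.0462, up to 0.9901 without other single libraries). The log2 fold change of Upk1a for UIRI d3 against Control turned from -1.82 to 0.02388 in block 1a (edgeR adjusted p = 0.984). At this depth edgeR recovered simulated 2-fold changes for 49 to 73 of 100 genes above a minimum mean count. Changes of 2-fold, above all at lower counts, and smaller changes can thus be missed.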

Other observations

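The tests of the gene lists in this part were chosen after values had been seen, so what follows are hypotheses found and tested on the same data. Genes of alternatively activated macrophages were higher with nephrectomy, with a median log2 fold change of 1.46 in the first cohort (4 of 12 measured genes rose, 8 adjusted over the list alone, adjusted p = 0.0217 with an estimated correlation) and 1.05 in the second (8 of 12 rose, 11 adjusted over the list alone, adjusted p = 0.00649 with an estimated correlation). Cd163, Arg1 and Lyve1 belong to this list. Genes of antigen presentation and interferon gamma were lower, with medians of -1.43 (8 of 17 fell, adjusted p = 0.0217 with an estimated correlation) and -0.59 (6 of 17 fell, adjusted p = 0.115 with an estimated correlation). Cd74, the invariant chain of class II molecules, fell by 2.30 on the log2 scale in the first and by 1.49 in the second cohort (edgeR adjusted p = 0.0014 and 0.0181), chosen after its values were seen.

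Glucocorticoid targets were higher with nephrectomy in the first cohort (9 of 18 rose, median 1.19, adjusted p = 0.0264 with an estimated correlation) and did not pass in the second (1 of 18 rose, median 0.35, adjusted p = 0.579 with an estimated correlation). Fkbp5, a target of the glucocorticoid receptor, had log2 fold changes of 1.88 and 0.42 (edgeR adjusted p = 0.0139 and 0.49), chosen after its values were seen. The 3 female-biased kidney genes had medians of 0.56 and -0.60 and did not pass in either cohort (camera adjusted p = 0.533 and 0.809 in limma); in the second cohort the mean had the opposite sign to the median.

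The column of no group, with 12446693 counts, also held Lcn2 at 153 CPM (exact Poisson 95% interval 146 to 160) and Mki67 at 20.4 (18 to 23.1). Col1a1 was at 464 (452 to 476) and Ptprc, the pan-leukocyte marker CD45, at 23.1 (20.5 to 26). Slc34a1, a phosphate transporter of the proximal tubule, was at 3070 CPM (3040 to 3100).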
